A study of Rattus norvegicus with 9 samples.

How the data were processed

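Gene expression was measured in the livers of 9 Wistar rats on a one-colour Affymetrix rat expression array. Per the labels, 36 rats were divided at random into a control group, a model group and a drug group of 12 rats each, and 3 rats drawn at random from each group were arrayed. All 9 animals carried the label male. What was done to the model rats and what the compound 7-P given to the drug group is were not given in the sources used here.

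The values used were the deposited signal intensities, 1 linear intensity for each probe set and array. Total RNA was labelled with biotin following the array maker's standard protocol, per the labels' protocols. GCOS 1.2 produced the signals, per the submitters' processing notes. Its settings and any scaling target were not given in the sources used here. The values showed no common scale, because the 2% trimmed mean of the signals lay between 33.5 and 81.1 across the arrays. No value was at or below 0.

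The written design, fixed before the data were examined, assumed signals already scaled between arrays and therefore planned no further normalization. Because the deposited signals were not scaled, quantile normalization of the log2 signals, which the design listed as an alternative, was made the main setting after the values were seen. The setting without normalization was kept as an alternative. Quantile normalization removes any true difference in the total amount of RNA between groups, and all changes are relative to it. With the arrays left unnormalized, the median difference of all probe sets was -0.40 (log2) in model against control, 0.06 in drug against model and -0.36 in drug against control. Scaling each array to 1 trimmed mean gave medians of 0.16, -0.06 and 0.07, and centring on the median gave -0.07, 0.02 and -0.07. In the main setting they were 0.02, -0.02 and -0.02.

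The table held 31099 probe sets, of which 57 control probe sets were left out. Among the other 31042 probe sets, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 were unnamed here. An Entrez identifier of the rat gene table matched 20758 of the single-gene probe sets, and 0 symbols changed through it. Probe sets with several symbols were tested but not named. Probe sets with a mean log2 signal at or above the 40th percentile were kept, which left 18625 probe sets and 10432 genes. This filter removes genes that are dim in all groups alike, so low transcripts are not covered. A signal of 1 probe set was not set against that of another.

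Differences were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend. All 9 arrays entered 1 fit with a term for each group, and the tests were two-sided. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over all 18625 probe sets. A moderated F test asked for any difference between the 3 groups. Gene groups were 33 lists of pathways, cell types and other tissues, written down with the design. Each gene was represented by its probe set with the highest mean signal. A list was tested with camera at a preset correlation of 0.01 between genes, adjusted over all 99 tests of 33 lists and 3 comparisons. Camera with an estimated correlation and fry served as alternatives. Camera asks whether a list moved relative to the other genes, while fry asks whether its genes moved on balance in 1 direction, and its mixed test whether they moved in either. With 3 arrays in a group, an exact permutation test between 2 groups cannot give a p under 0.1. The number of arrays limits the precision of every value.

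Genes were to be named by a fixed rule. For model against control and drug against model it took the 12 higher and 12 lower genes with the largest change among those past the threshold and without overlap between the groups. For drug against control it took 6 and 6. Places left open were filled by the smallest unadjusted p, and since no probe set passed, all were. From each list the rule took up to 4 members past the threshold over all probe sets, or otherwise the 2 with the smallest unadjusted p. Other genes, among them Xist, Eif2s3y and the further list members that passed when adjusted over the list alone, were chosen after their values were seen.

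RNA quality was read from the array's control probe sets as the ratio of the signal at the 3' end to that at the 5' end of Gapdh and of beta-actin. A higher ratio means that less of the 5' end was measured. Further alternatives were median centring, an offset of 2.88 signal units before the log, no filter, a 60th percentile filter, no intensity trend, array weights, only the groups compared, the replicate block, a per-probe-set test without moderation, 1 probe set per gene, the mean of a gene's probe sets, a minimum fold of 2, and each array left out in turn. Chosen after seeing the data were scaling to 1 trimmed mean, a term for the log2 Gapdh ratio, leaving out control 1 and drug 1, leaving out control 2 and drug 3, and a term for control 2 and drug 3. The setting without normalization belongs to neither kind, since it had been the planned main setting.

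The procedure was tested on simulated data with the spread of these arrays, with 50 probe sets changed at each fold. The noise was drawn independently for each probe set and array. Structure shared by many probe sets, such as RNA quality, was thus not simulated, and the shares recovered hold only without it. In model against control it recovered 4% of 2-fold, 56% of 4-fold, 68% of 8-fold and 82% of 16-fold changes. In drug against model the shares were 2%, 46%, 86% and 80%. In drug against control they were 6%, 42%, 76% and 90%. Unchanged probe sets called in these comparisons numbered 8, 4 and 10. Figures were drawn with matplotlib 3.10.9.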

Results

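The study measured liver RNA of 9 Wistar rats, 3 from a control group, 3 from a model group and 3 from a drug group that received 7-P. The comparisons ask what differed in the model livers, what differed between drug and model livers, and how far the drug livers stood from the control livers. Trimmed mean signals before normalization were 81.1, 34.5 and 67.4 in control 1, 2 and 3. They were 43.8, 34.9 and 38.4 in the model arrays and 66.9, 33.9 and 33.5 in the drug arrays. Differences below are log2 differences of normalized signal, with the standard error (SE) of the limma fit where 1 gene is concerned.

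The 3' to 5' signal ratios, used here to read RNA quality, differed between arrays. The integrity of the RNA was not measured in another way. The Gapdh 3' to 5' signal ratio was 1.52, 3.14 and 3.07 in control 1, 2 and 3, with a mean of 2.58 ± 0.915 (SD, n = 3). It was 4.09, 12.7 and 9.77 in the model arrays, 8.85 ± 4.37 (SD, n = 3), and 1.31, 9.20 and 8.71 in the drug arrays, 6.41 ± 4.42 (SD, n = 3). Every model array lay above every control array (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Over the 3 groups the exact permutation p was 0.221, or 0.629 adjusted over 5 array measures. The beta-actin ratio averaged 6.74, 10.3 and 8.03 in control, model and drug arrays, but did not separate model from control (exact permutation p = 0.3). Model 3, at 7.31, lay below control 2 (8.41) and control 3 (7.59). Model 1, with the lowest Gapdh ratio of the model arrays, had the highest beta-actin ratio of them, 12.8. Inside the groups, 2664 of the 18625 probe sets (14.3%) followed the Gapdh ratio at a limma adjusted p under 0.05, 1426 upward and 1238 downward. The main principal component held 36.6% of the variance, with control 1 at -87.0 and drug 1 at -82.3, the arrays with the lowest ratios, and model 3 at 68.5 on the far side.

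**Figure D1:**
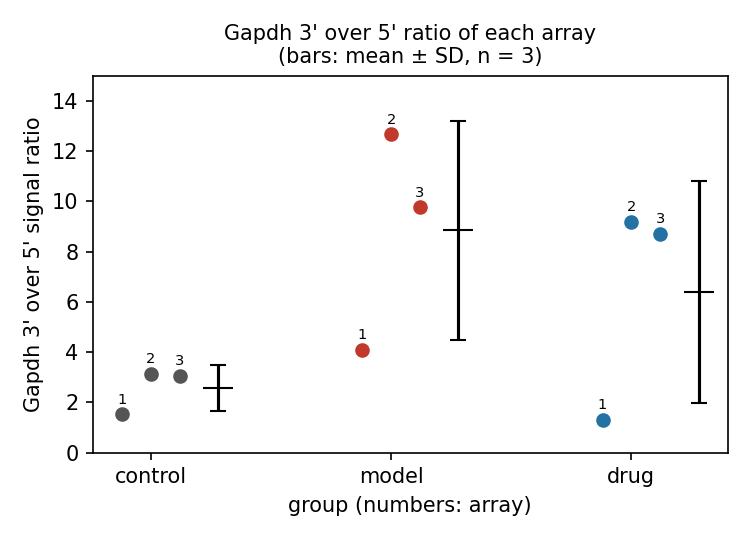
Gapdh 3' over 5' signal ratio of each array (points) by group, with the group mean and standard deviation (n = 3). The 3 model arrays lie between 4.09 and 12.7, above all control arrays, and drug 1 at 1.31 is the lowest array.

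Sex-linked transcripts divided the arrays in another way. Xist, the X-linked RNA that silences an X chromosome in females, had a log2 signal of 0.765 in control 2 and 0.943 in drug 3, and between 7.77 and 10.6 in the other 7 arrays. Eif2s3y, a Y-linked gene, went the other way, at 6.99 and 7.17 in control 2 and drug 3 and at most 2.53 elsewhere. Its probe set lies below the filter. Cyp2c11, a male-specific steroid hydroxylase of rat liver, was at 11.3 and 12.1 in control 2 and drug 3 and between 2.87 and 5.22 in the others. Cyp2c12, the female-specific counterpart, was at 5.82 and 8.19 against 11.9 to 12.4. Of 5 Y-linked probe sets with 1 gene, only Uty passed the filter, and its signal in these arrays, 6.19 and 5.71, was not above the others. All 9 animals were labelled male.

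**Figure D2:**
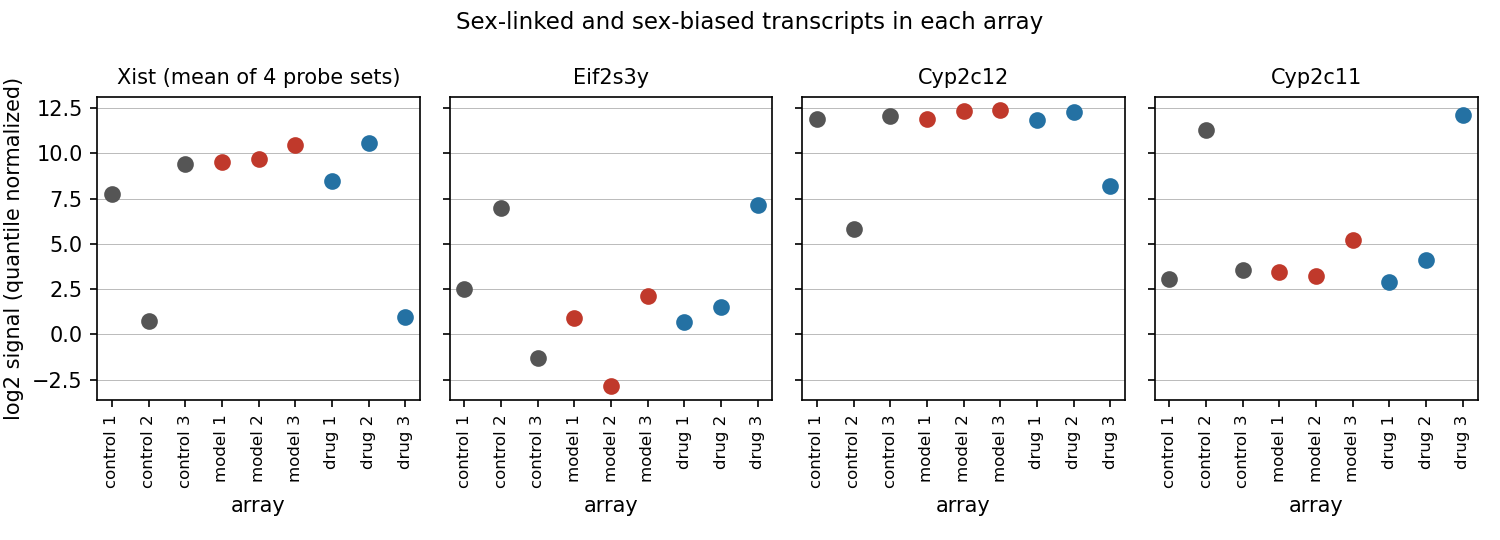
Log2 signal of Xist (mean of 4 probe sets), Eif2s3y, Cyp2c12 and Cyp2c11 in each array, coloured by group. Control 2 and drug 3 stand apart from the other 7 arrays in all 4 panels, low in Xist and Cyp2c12 and high in Eif2s3y and Cyp2c11.

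The list results from here on are camera calls at the preset correlation of 0.01. With an estimated correlation, or with the fry test of 1 direction, 0 lists passed in each comparison. The estimated correlation was 0.42 for oxidative phosphorylation, 0.56 for macrophages and 0.78 for cholesterol synthesis. In each comparison 6 of 10 splits of the same arrays, the real one included, gave as many lists. By the preset calls, macrophage and inflammatory transcripts were higher in model than in control livers. Of 17 measured Kupffer cell and macrophage genes, 14 were higher, with a median of 0.72, among them the scavenger receptor Cd163 at 1.25 (SE 0.253) and the Fc receptor chain Fcer1g at 1.1. The list passed (camera adjusted p = 0.00075), with an adjusted p = 0.647 with an estimated correlation. Of 17 cytokine and chemokine genes 14 were higher, with a median of 0.27, among them the interleukin Il1b at 1.67 and the chemokine Ccl6 at 1.63 (camera adjusted p = 0.0292, and adjusted p = 0.647 with an estimated correlation). Of 5 neutrophil genes 4 were higher, with a median of 1.66, among them S100a9 at 2.83 and the receptor Csf3r at 1.66 (camera adjusted p = 0.0436, and adjusted p = 0.647 with an estimated correlation). The control level of Csf3r lay under the filter, near background, so its size is not exact. Adjusted over the list alone, 1 macrophage gene (Cd163), 2 cytokine genes (Il1b and Ccl6) and 0 neutrophil genes passed in limma, and 0 genes of these lists passed over all probe sets. Of the neutrophil and cytokine genes, 3 and 4 had an unadjusted p under 0.05. With the Gapdh term the medians were 0.99 for macrophages, 0.37 for cytokines and 2.16 for neutrophils, the last with an adjusted p of 0.104. Without normalization the macrophage median was 0.23 and the cytokine median turned to -0.10, where the median of all probe sets was -0.40. The cytokine call ended without control 2 (median 0.16, adjusted p = 0.184), model 1 (0.38, 0.0907), model 2 (0.32, 0.0601) or drug 1 (0.27, 0.0612), and its median was 0.77 without model 3. The neutrophil call ended without control 2 (0.98, 0.141), model 1 (1.84, 0.117), model 3 (1.47, 0.0596) or drug 1 (2.11, 0.10). With control 2 and drug 3 left out together, the cytokine median was 0.16 (adjusted p = 0.222) and the neutrophil median 0.98 (0.135), and with a term for these arrays they were 0.31 (0.0912) and 1.75 (0.110), so both calls ended. The 60th percentile filter ended the neutrophil call (2.71, 0.0772). The neutrophil median was 1.04 with an offset before the log, and the cytokine median 0.46 with the trimmed mean and 0.45 with the stricter filter.

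At the preset correlation, mitochondrial, antioxidant, chaperone and nitrogen metabolism transcripts were lower in the model livers. Of 39 oxidative phosphorylation genes 35 were lower, with a median of -0.58, among them the ATP synthase subunit Atp5f1d at -0.76 and the complex I subunit Ndufv1 at -0.84 (camera adjusted p = 1.66e-06, and adjusted p = 0.647 with an estimated correlation). Of 18 antioxidant enzymes 14 were lower, with a median of -0.51, including the peroxiredoxins Prdx4 at -1.41 and Prdx6 at -1.01 (camera adjusted p = 0.00996, and adjusted p = 0.647 with an estimated correlation). Of 17 heat shock genes 14 were lower, with a median of -0.33, among them the cochaperones Fkbp4 at -0.97 and Dnajb1 at -0.57 (camera adjusted p = 0.0292, and adjusted p = 0.647 with an estimated correlation). Of 26 urea cycle and amino acid catabolism genes 19 were lower, with a median of -0.23 (camera adjusted p = 0.0488, and adjusted p = 0.647 with an estimated correlation). The genes that passed when adjusted over the list alone numbered 2 in the last list, the urea cycle enzyme Ass1 at -1.02 and the alanine transaminase Gpt at -1.81. In the other 3 lists 0 genes passed in limma adjusted over the list alone, with 18, 4 and 2 genes at an unadjusted p under 0.05. The Gapdh ratio was higher in every model array than in every control array, and with its term the medians were -0.17 for oxidative phosphorylation (adjusted p = 0.0456), -0.18 for antioxidants (0.445), -0.26 for heat shock (0.445) and -0.17 for the urea cycle (0.229). Without normalization the 4 medians were -1.36, -1.17, -0.92 and -0.97, where that of all probe sets was -0.40, and with median centring they were -1.03, -0.84, -0.59 and -0.64. The antioxidant call ended without model 3 (median -0.31, adjusted p = 0.0529), and its median was -0.82 without model 1. The heat shock call ended without control 1 (-0.25, 0.0891), model 1 (-0.38, 0.121) or model 3 (-0.29, 0.0529), and its median was -0.54 without control 2 and -0.52 without model 2. It also ended with the 60th percentile filter (-0.30, 0.0588), without control 1 and drug 1 (-0.23, 0.146) and without control 2 and drug 3 (-0.54, 0.0623). The urea cycle call ended without control 1 (-0.19, 0.105), control 2 (-0.34, 0.0623), model 1 (-0.17, 0.101), model 2 (-0.26, 0.0633), drug 1 (-0.23, 0.0624) or drug 3 (-0.23, 0.0539), and its median was -0.34 without control 3. It also ended with no filter (-0.23, 0.0502), the 60th percentile filter (-0.23, 0.0514), without control 1 and drug 1 (-0.20, 0.122), without control 2 and drug 3 (-0.34, 0.0787) and with a term for the latter (-0.21, 0.126). Its median was -0.41 with the trimmed mean and -0.35 with the mean of a gene's probe sets.

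No single probe set passed in model against control. Siglec5, a sialic acid receptor of myeloid cells, was higher by 2.71 (SE 0.340) and Igsf6, another immune cell receptor, by 2.45 (SE 0.349), with limma adjusted p of 0.219 and 0.329. Fmo1, a flavin monooxygenase, was at 8.11 ± 1.09 in control and 5.02 ± 0.329 in model livers (SD, n = 3), a difference of -3.09 (SE 0.465) with a limma adjusted p of 0.359. Other genes with model values above all control values were Slfn9 (2.70), Thumpd3-as1 (2.37), Tmem106a (2.07), Arhgap9 (1.94), Snx10 (1.88), the growth arrest ligand Gas6 (1.79), Nfkbiz (1.78) and the leukocyte phosphatase Ptprc (1.46). Lower were the homeobox gene Dlx3 (-3.17), Dnph1 (-2.44), Tmem254 (-1.76), Serpina4 (-1.62), Cdip1 (-1.53), Mmp19 (-1.40), Ethe1 (-1.39), Smagp (-1.34), Id2 (-1.30), Banf1 (-1.24) and the hepatic lipase Lipc (-1.11). The model level of Dlx3 lay under the filter, near background, so its size is not exact, and with an offset before the log it was -2.02. The control level of Igsf6 also lay under the filter. These genes had limma adjusted p between 0.219 and 0.373. At an unadjusted p under 0.05 there were 2245 probe sets, 1213 higher and 1032 lower, where 931 are expected by chance. Leaving out each array in turn gave between 1157 (without model 3) and 3259 (without drug 1). The unmoderated test called 2 probe sets, Gpr19 at 1.16 (adjusted p = 0.0147) and Aqp11 at -1.25 (0.0153). Groups without overlap made up 22.6% of the probe sets, against 10% by chance. Structure shared by many probe sets can move such counts far from these chance values, here and in the comparisons below. Every model array had a higher Gapdh ratio than every control array, and with the Gapdh term the unadjusted count was 1573. Other splits of these arrays gave unadjusted counts from 292 to 1286.

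**Figure D3:**
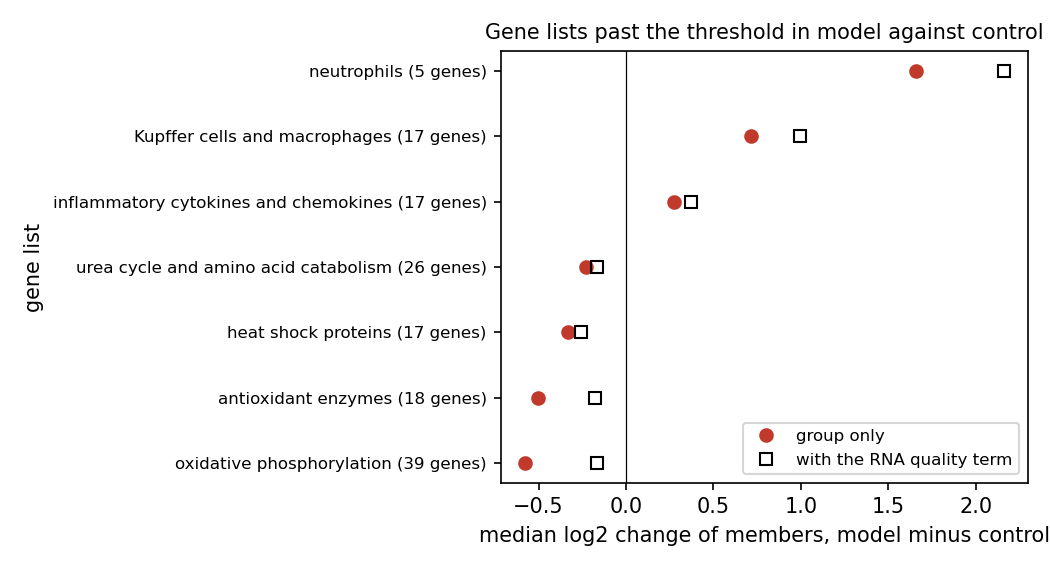
Median log2 difference, model minus control, of the lists past the camera threshold in model against control, with and without a term for the Gapdh ratio. Oxidative phosphorylation in model against control moves from -0.58 to -0.17 with the term, while the macrophage list moves from 0.72 to 0.99.

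Drug livers had higher lipogenic transcripts than model livers and lower cholesterol synthesis and endothelial transcripts. Of 23 fatty acid and triglyceride synthesis genes 19 were higher, with a median of 0.52, among them the lipogenic regulator Srebf1 at 1.28 (SE 0.379) and the liver pyruvate kinase Pklr at 1.38 (camera adjusted p = 0.00109, and adjusted p = 0.647 with an estimated correlation). Of 20 cholesterol synthesis genes 18 were lower, with a median of -0.60, among them Hsd17b7 at -1.40 and the isomerase Idi1 at -1.74 (camera adjusted p = 0.00107, and adjusted p = 0.647 with an estimated correlation). Of 17 sinusoidal endothelium genes 14 were lower, with a median of -0.32, among them the hyaluronan receptor Lyve1 at -1.24 and the receptor Gpr182 at -0.82 (camera adjusted p = 0.00126, and adjusted p = 0.647 with an estimated correlation). Adjusted over the list alone, 0 genes of these lists passed in limma, with 3, 1 and 4 genes at an unadjusted p under 0.05. The cholesterol shift rested on drug 3, an array low in Xist, without which the median was -0.06 and the camera direction turned (adjusted p = 0.861). Hsd17b7 was then -0.65 and Idi1 -0.53. With control 2 and drug 3 left out the median was -0.06 (0.801), with a term for them -0.20 (0.308), and without drug 2 it was -0.95. The lipogenic call ended without model 1 (median 0.27, adjusted p = 0.111), where Pklr was 0.87. The endothelial call ended without model 1 (-0.33, 0.101), and its median was -0.67 without model 3, -0.54 without drug 1, -0.52 without drug 2 and -0.53 without control 1 and drug 1. The cholesterol median was -0.38 without normalization. With the Gapdh term the medians were 0.56, -0.70 and -0.50.

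At the preset correlation, interferon and conjugation transcripts were also higher in drug than in model livers, and male-predominant transcripts through drug 3. Drug 3 was low in Xist and high in Eif2s3y, as no model array was. The male-predominant list score was 4.03 in drug 3. In drug 1 (-1.16) and drug 2 (-0.979) it lay within the model arrays (-1.79 to -0.646). Of 26 interferon and antigen presentation genes 18 were higher, with a median of 0.16, among them Irf7 at 1.04 and Isg15 at 0.99 (camera adjusted p = 0.0150, and adjusted p = 0.647 with an estimated correlation). Of 26 conjugation and NRF2 target genes 17 were higher, with a median of 0.18, among them the glutathione transferases Gstm4 at 1.18 and Gstm7 at 0.95 (camera adjusted p = 0.0322, and adjusted p = 0.647 with an estimated correlation). Of 13 male-predominant liver genes 12 were higher, with a median of 1.86 (camera adjusted p = 0.00417, and adjusted p = 0.647 with an estimated correlation). Of these, the steroid dehydrogenase Hsd17b2 passed adjusted over the list alone, at 2.49 (SE 0.503), while in the other lists 0 genes passed in limma, with 3 and 2 at an unadjusted p under 0.05. The male-predominant call ended without drug 3 (median 0.06, adjusted p = 0.474), without control 2 and drug 3 (0.08, 0.442) and with a term for them (-0.03, 0.652), and its median was 2.83 without drug 1, 2.82 without control 1 and drug 1, and 3.04 without drug 2. The interferon call ended without model 1 (0.26, 0.0568), model 3 (0.12, 0.0670), drug 1 (0.15, 0.101) or drug 3 (0.15, 0.123), without control 1 and drug 1 (0.15, 0.0893) and without control 2 and drug 3 (0.15, 0.146), and its median was 0.25 without drug 2. The conjugation call ended without model 2 (0.14, 0.212), drug 1 (0.05, 0.621) or drug 3 (0.22, 0.0913), without control 1 and drug 1 (0.05, 0.679), without control 2 and drug 3 (0.22, 0.106) and with a term for the latter (0.15, 0.0742), and its median was 0.49 without drug 2. Gstm4 was 0.74 without drug 1 and Gstm7 0.39 without drug 3. Without normalization the interferon and conjugation medians were 0.28 and 0.34, and with median centring 0.24 and 0.30. With the Gapdh term the medians were 0.14 for interferon (adjusted p = 0.0637), 0.10 for conjugation (0.445) and 2.41 for male-predominant genes.

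Among single genes in drug against model, Fmo1 stood at 8.50 ± 0.240 in drug livers (SD, n = 3), 3.47 (SE 0.465) above the model livers, with a limma adjusted p of 0.400. No probe set passed, and the other genes here had a limma adjusted p of 0.998. Higher in every drug array than in every model array were Dlx3 (2.82), Htr1b (2.0), Xrcc1 (1.60), Mid1ip1 (1.56), Farp1 (1.51), a Srebf1 probe set (1.51), Xpnpep2 (1.22), Cdv3 (1.22), Arrdc3 (1.13) and Serpina4 (1.03). Lower were Kiaa1755 (-2.82), Ctsw (-2.25), Pcdh18 (-1.80), the phospholipid transfer protein Pltp (-1.68), Snx10 (-1.46), Gas6 (-1.45), the hormone-sensitive lipase Lipe (-1.40), Snx8 (-1.12), Stk35 (-1.04), Hipk1 (-0.92), Ptprj (-0.91) and Ets1 (-0.87). The lower group lay near background in Dlx3, Htr1b, Kiaa1755 and Ctsw, so these sizes are not exact, and with an offset Dlx3 was 1.72 and Kiaa1755 -1.77. The xenobiotic-inducible Cyp1a1 was lower by a difference of -3.87 (SE 0.990), also to a level near background. There were 610 probe sets at an unadjusted p under 0.05, 274 higher and 336 lower, fewer than the 931 expected by chance, and the unmoderated test called 0. With each array left out in turn, the count lay between 430 (without model 2) and 1083 (without drug 2), the latter above chance. Groups without overlap made up 8.05% of the probe sets, against 10% by chance.

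Drug livers differed from control livers in clock transcripts. Adjusted over the list alone, 9 of 16 clock genes passed in limma, and over all probe sets 0 did. The genes that rose were Per3 (5.46), Nr1d1 (3.35, SE 0.594), Dbp (3.12), Nr1d2 (2.92), Per2 (2.55) and Tef (1.04), where Per3 was near background in the control arrays. The genes that fell were Bmal1 (-1.89), Cry1 (-1.45) and Nfil3 (-1.43), members of the opposite arm of the clock. Because the members went both ways the list did not pass camera (median 0.40, adjusted p = 0.0695), while the mixed fry test gave an adjusted p of 0.0281. A score of the difference between the arms, 9 genes against 5, chosen after the values were seen, was -2.35 ± 0.404 in control, -0.67 ± 1.33 in model and 0.81 ± 0.976 in drug livers (SD, n = 3, exact permutation p over the 3 groups = 0.0393, the smallest possible being 0.00357). The pairwise exact permutation p were 0.1 for drug against control, 0.1 for model against control and 0.2 for drug against model, where the smallest possible is 0.1. Drug minus control was 3.16, and 2.80 without drug 3.

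**Figure D4:**
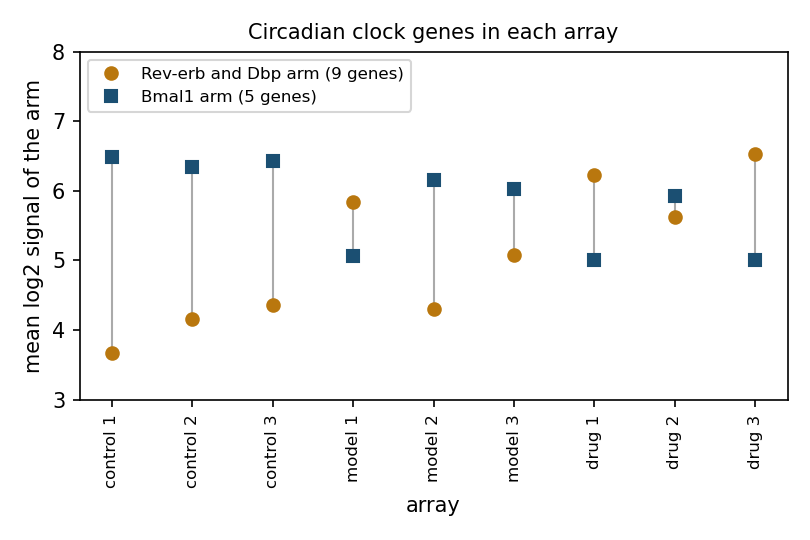
Mean log2 signal of the 2 arms of the clock genes in each array, the Rev-erb and Dbp arm (9 genes) and the Bmal1 arm (5 genes). The first arm minus the second averages -2.35 in control, -0.67 in model and 0.81 in drug arrays. This difference is higher in every drug array than in every control array.

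By camera at the preset correlation, macrophage transcripts were higher in drug than in control livers, and oxidative, antioxidant and chaperone transcripts lower. Of 17 macrophage genes 16 were higher, with a median of 0.44, among them Cd163 at 1.18 and the oxidase subunit Cybb at 0.99 (camera adjusted p = 0.00126, and adjusted p = 0.647 with an estimated correlation). Of 39 oxidative phosphorylation genes 35 were lower, with a median of -0.39, among them Ndufb10 at -0.94 and Atp5f1d at -0.64 (camera adjusted p = 0.000106, and adjusted p = 0.647 with an estimated correlation). Of 18 antioxidant enzymes 15 were lower, with a median of -0.46, including Txn2 at -0.98 and Prdx6 at -0.79 (camera adjusted p = 0.00996, and adjusted p = 0.647 with an estimated correlation). Of 17 heat shock genes 15 were lower, with a median of -0.38, among them Fkbp4 at -1.32 (camera adjusted p = 0.00328, and adjusted p = 0.647 with an estimated correlation). Adjusted over the list alone, Cd163 and Fkbp4 passed, while 0 oxidative phosphorylation and 0 antioxidant genes passed in limma, with 5 and 2 at an unadjusted p under 0.05. The macrophage call ended without control 2 (median 0.22, adjusted p = 0.0866), drug 1 (0.20, 0.353) or control 1 and drug 1 together (0.21, 0.294), and its median was 0.69 without control 3. The antioxidant call ended without drug 2 (-0.42, 0.0521) and without control 2 and drug 3 (-0.33, 0.0623). Txn2 was -0.62 without drug 2. The oxidative phosphorylation median was -0.21 without drug 2, and the heat shock median -0.57 without drug 1. Without normalization, where the median of all probe sets was -0.36, the medians were 0.11 for macrophages, -1.0 for oxidative phosphorylation, -0.99 for antioxidants and -0.82 for heat shock. With median centring oxidative phosphorylation was at -0.72 and antioxidants at -0.70. The Gapdh ratio was higher in drug 2 and drug 3 than in every control array and lower in drug 1. With its term the medians were 0.67 for macrophages, -0.23 for oxidative phosphorylation (adjusted p = 0.0291), -0.22 for antioxidants (0.122) and -0.33 for heat shock (0.0388).

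Fatty acid genes shifted in both directions between drug and control livers at the preset correlation. Of 27 fatty acid oxidation and PPAR-alpha target genes 21 were lower, with a median of -0.50, among them Cyp4a3 at -0.77 and the lipid droplet protein Plin2 at -0.69 (camera adjusted p = 0.0137, and adjusted p = 0.647 with an estimated correlation). Of 23 fatty acid and triglyceride synthesis genes 14 were higher, with a median of 0.45, among them Srebf1 at 1.04 and the citrate lyase Acly at 1.09 (camera adjusted p = 0.0385, and adjusted p = 0.647 with an estimated correlation). When adjusted over the list alone, 0 genes of either list passed in limma, with 3 and 3 at an unadjusted p under 0.05. The oxidation call ended without control 1 (median -0.39, adjusted p = 0.0890), drug 3 (-0.24, 0.127) or control 2 and drug 3 together (-0.37, 0.0623), and with the Gapdh term (-0.16, 0.161). Its median was -0.77 without drug 1, -0.27 without drug 2, -1.05 without normalization and -0.76 with median centring. Without drug 3, Cyp4a3 was -0.44 and Srebf1 0.63, and without control 2 Acly was 0.66. The synthesis call ended without control 2 (-0.01, 0.656), drug 1 (0.29, 0.174) or control 2 and drug 3 together (0.15, 0.504), and with the Gapdh term (0.34, 0.0637), and its median was 0.25 without drug 2. It ended without normalization too, with a median of -0.08 where that of all probe sets was -0.36 (adjusted p = 0.0587). The call also ended with median centring (0.21, 0.137), the trimmed mean (0.36, 0.197), the 60th percentile filter (0.13, 0.0531), the mean of a gene's probe sets (0.37, 0.0646) and without control 1 and drug 1 (0.39, 0.0762).

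No single probe set passed in drug against control, where the lowest limma adjusted p was 0.676, shared by the genes named here. Beside Nr1d1 and Nr1d2, every drug array exceeded every control array in H2-Q7-ps1 (4.41), the helicase Ddx60 (2.37), Thumpd3-as1 (2.28) and Zfp758 (1.83). Lower were Kiaa1755 (-2.80), Epn1 (-1.54), the apolipoprotein Apoa4 (-1.29, SE 0.255), Mul1 (-1.26), Gpr182 (-1.20) and Tmem276 (-1.15). The lower group lay near background in H2-Q7-ps1, Ddx60 and Kiaa1755, and with an offset H2-Q7-ps1 was 2.93 and Kiaa1755 -1.74. At an unadjusted p under 0.05 there were 1345 probe sets, 781 higher and 564 lower, where 931 are expected by chance, and the unmoderated test called 0. That count was 3752 without drug 1, but below chance without drug 3 (728), drug 2 (749) or control 2 (892). Groups without overlap made up 12.5%, against 10% by chance. The F test over the 3 groups called 0 probe sets in limma (lowest adjusted p 0.387), with 1387 at an unadjusted p under 0.05.

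Genes that were apart in the model livers were compared in the drug livers. Of the probe sets at an unadjusted p under 0.05 in model against control, 244 were so in drug against model in the opposite direction, Fmo1 and Dlx3 among them, and 1 in the same direction. The model arrays enter both comparisons with opposite signs, and simulated unchanged groups gave 232.2 opposite and 3.98 in the same direction. Independent lists would give 21.9 higher then lower and 15.2 lower then higher. The covariance of the differences was -0.208 against -0.134 in simulated groups, a difference of -0.0741, and 24 of 100 assignments of the arrays, the real one included, gave a value at or below it. The correlation across probe sets, which are not independent replicates, was -0.558 against -0.500. For model and drug livers against the same control arrays, 697 probe sets were shared in direction and 0 opposed, where simulated groups gave 225.42. That covariance was 0.303 against 0.134, a difference of 0.169, and 12 of 100 assignments, the real one included, gave a value at or above it. Independent lists would share 50.9 higher and 31.3 lower. In simulated unchanged groups the shared arrays alone gave 232.2 opposed probe sets, near the 244 measured, so that overlap is no evidence of a reversal. The 3 arrays cannot be split into parts of 2 or more. Part of the excess of the 697 shared probe sets over independent lists may thus come from the shared arrays, which gave 225.42 in simulated groups.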

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

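All tests of an explanation in this part were chosen after the result was seen. The ratio of control probe sets, which are not among the probe sets tested for expression and enter a fit only through the Gapdh term, was above the level of the control group. The mean Gapdh 3' to 5' ratio was 8.85 in the model group against 2.58 in the control group, where the exact permutation p of 0.1 is the smallest possible. The beta-actin ratio did not separate these groups (exact permutation p = 0.3).

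RNA quality may account for most of the lower oxidative phosphorylation list in model against control: inside the groups the list went down with the ratio (camera adjusted p = 0.00072), and with the Gapdh term its median was -0.166 instead of -0.575. That remainder still passed camera (adjusted p = 0.0456), and as every model array had a higher ratio than every control array, a part due to the model treatment stays open. For the higher macrophage list RNA quality stays open. Inside the groups its direction with the ratio was down (camera adjusted p = 0.0959), and its median was larger, 0.995, with the term. That direction was not shared by all groups. Drug 1, with the lowest ratio, had a list score of 0.741, against -0.14 in drug 2 and -0.251 in drug 3. Among the model arrays model 2, with the highest ratio, scored highest, at 0.762, against 0.157 in model 1 and -0.078 in model 3. A lower share of hepatocyte RNA would raise all other cell types alike. The macrophage score moved away from the mean of the endothelial, stellate and bile duct scores by 0.800 (SE 0.285). The macrophage score itself rose by 0.678 (SE 0.340), and its value in model 3 (-0.078) lay below that in control 3 (-0.037). The bile duct score, at -0.417 (SE 0.425), widened the gap. The values thus argue only weakly against a lower hepatocyte share. The gap carried no Gapdh term. With the term the endothelial list rose too (median 0.46, camera adjusted p = 0.0434), while the stellate and bile duct medians were 0.02 and -0.03. A change in the macrophages themselves was not tested, and these values do not separate their share from their activity.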

How the results depend on the processing

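The tests chosen after the result was seen were scaling to 1 trimmed mean, the Gapdh term, leaving out control 1 with drug 1, leaving out control 2 with drug 3, and the term for control 2 and drug 3. No normalization had been the planned main setting. For genes named by the fixed rule, 6077 values were compared, of which 6035 kept their direction without passing, 13 passed and 29 reversed. Genes chosen after their values were seen, such as Per3 in drug against control, are not in these counts. For list calls, 303 of 418 values stayed past the threshold, 113 did not and 2 reversed in camera direction. Of 247 differences of genes named by the fixed rule, 93 fell under the main value divided by 1.5 with some array left out, 33 rose over 1.5 times it, and 14 fell so far with the offset. In 27 the lower group lay under the filter level. Where no cause is given, the cause was not tested. The number of arrays, and signals near background, limit all values.

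Against 0 probe sets in the main setting, limma called 1 in model against control and 1 over the 3 groups without normalization, 4 in model against control with array weights, 1 in drug against model with only the groups compared, and 1 each in model against control, drug against model and over the 3 groups without control 1 and drug 1. The unmoderated test called 2 in model against control. With each array left out, counts lay between 0 and 1 in model against control, drug against model and over the 3 groups, and were 0 throughout in drug against control, where the unadjusted count was 1345. Fmo1 was the probe set called in most of these, as in model against control without control 1 (-3.66, adjusted p = 0.0145).

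The replicate block gave 3 probe sets in model against control (Siglec5, Thumpd3-as1 and Scd, adjusted p = 0.0425). The number did not pair all arrays: 5 of 9 same-numbered pairs had deviations correlated above 0.1 (from -0.00522 to 0.482). The 3 of 9 arrays that correlated best with their own number were control 1, model 1 and drug 1, so these went together. Control 1 correlated at 0.195 with model 1 and 0.482 with drug 1, and model 1 at 0.389 with drug 1. Each also had the lowest Gapdh ratio of its group. The block changed no other call of probe sets, but the counts at an unadjusted p under 0.05 were 3633, 1082 and 2235 with it.

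Lists past the threshold, 7, 6 and 6 in model against control, drug against model and drug against control, were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. Without normalization there were 11 in drug against model and 11 in drug against control. Model against control had 12 with median centring, 12 with the trimmed mean, 4 with the stricter filter and 4 without control 2 and drug 3. Drug against model had 10 with the trimmed mean, 2 without control 2 and drug 3 and 3 with their term. With each array left out the counts ranged from 3 to 11, 2 to 9 and 4 to 11. The reversal correlation was -0.270 without control 1 and drug 1, and from -0.700 to -0.177 with each array left out.

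The camera direction of the cholesterol list in drug against model turned without drug 3 (median -0.0608, adjusted p = 0.861, where the lowest median was -0.950 without drug 2) and without control 2 and drug 3 (-0.0599, 0.801), while the median stayed below 0. Genes that had not passed reversed as follows. Without normalization, where the median of all probe sets was lower in model and drug, these were Nsdhl (-0.105), Hsd17b4 (-0.438), Pck1 (-0.148), Cp (-0.0164), Hsp90b1 (-0.264), Mcl1 (-0.115), Ier3 (-0.143) and Tfr2 (-0.0918) in model against control, and Sc5d (-0.0739) and Slc39a14 (-0.159) in drug against control. Median centring reversed Hsd17b4 (-0.108). The Gapdh term reversed Aqp1 (0.651), Mcm7 (-0.0335), Dhrs7 (0.119) and Hbb (0.488) in model against control and Dhrs7 (0.168) in drug against control. Leaving out control 1 and drug 1 reversed Aurka (0.0425), leaving out control 2 and drug 3 reversed Cpa1 (1.21) and Cpb1 (0.0305), and their term Cpa1 (1.54). With each array left out, the values ranged from -0.199 (without control 2) to 0.626 for Cfd, -0.612 to 0.0449 (without control 3) for Ier2, -0.380 to 0.145 (without model 2) for Cpb1, also 0.0295 without drug 3, -0.0863 (without model 3) to 1.17 for Slc4a1, -0.449 to 0.00947 (without drug 2) for Cidec, -0.994 to 0.0725 (without drug 2) for Dhrs7, -2.86 to 1.22 (without drug 3) for Cpa1, and -0.669 to 0.0295 (without drug 3) for Pmvk.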

Other observations

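Of 18 lipoprotein genes, 3 passed adjusted over the list alone: in model against control the phospholipid transfer protein Pltp rose by 1.39, while the hepatic lipase Lipc (-1.11) and the apolipoprotein Apoa4 (-1.05) fell. The list as a whole did not pass camera (median -0.20, adjusted p = 0.219), while the mixed fry test gave an adjusted p of 0.0171. Pltp fell in drug against model (-1.68), also adjusted over the list alone. Of 20 cholesterol synthesis genes 17 were higher in the model livers, with a median of 0.59 that missed the threshold (adjusted p = 0.0512). It was 0.78 with the Gapdh term (0.000789), but 0.37 without control 2, an array low in Xist (0.333), 0.10 with the term for control 2 and drug 3 (0.870), and -0.21 without normalization (0.175). The desaturase Scd was at -2.25 and the bile acid exporter Abcc3 at 2.43, neither passing. As the control level of Abcc3 lay under the filter, near background, its size is not exact.

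Single genes of other lists passed adjusted over the list alone, while the lymphocyte (adjusted p = 0.0794) and acute-phase (0.745) lists did not pass camera in model against control. With the Gapdh term the acute-phase list did, at a median of 0.28 (adjusted p = 0.0291). Ptprc of the lymphocyte list rose by 1.46 in model and 1.38 in drug against control, and Il1r1 (1.67) of the acute-phase list and the zinc transporter Slc39a14 (0.84) rose in model against control. In drug against control, Il18 (1.59), Ccl6 (1.34) and Il1b (1.12) rose, and the p53 target Phlda3 (-1.60) fell, each adjusted over the list alone. Dbp rose in drug against model (3.22) by the same standard. Hepatocyte genes had medians of -0.13, 0.03 and -0.08 in model against control, drug against model and drug against control, and extracellular matrix genes -0.15, -0.14 and -0.24, none past the threshold.

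The tests of sex and of the clock were chosen after the result was seen, while the counts over other splits were planned. Control 2 and drug 3 stood apart in Xist, Eif2s3y and the male- and female-predominant lists. An effect of the treatment would leave the control arrays alike, but the measured Xist signals of control 1 and control 3 lay 7.01 (log2) or more above control 2, and 4.95 or more above the filter level, under which control 2 lies near background. The values argue against RNA quality too, as arrays of 1 group with nearly equal Gapdh ratios had measured Xist signals 8.66 or more apart, or 6.61 from the filter level. Rats of both sexes under the label male is a candidate explanation, since all 4 measures placed 9 of 9 arrays alike, 7 with high Xist and 2 with low. Samples taken from other animals stay open. The estrogen sulfotransferase Sult1e1, written into the female-predominant list, was high in control 2 and drug 3 (12.0 and 12.1) and at most 4.97 elsewhere. It thus went with the male-predominant genes such as Cyp2c11. Its place in the list, left as written, is in question, so it is not counted against a difference of sex.

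In the clock genes, the values argue against RNA quality as the whole of the difference between drug and control livers, as the arm score was 3.55 (SE 0.849) with the Gapdh term and 3.16 without. It did not rest on drug 3, since the lower of drug 1 and drug 2 lay 1.75 above the highest control array, and without control 2 and drug 3 the difference was 2.89. Of 14 genes, 12 went in the direction of their arm, which another time of day at killing could give. The score was 1.68 higher in model than in control livers and 1.48 higher in drug than in model livers (exact permutation p = 0.1 and 0.2, the smallest possible being 0.1), and as the labels give no time, time of day cannot be told apart from the model treatment or from 7-P.

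Other splits of the arrays were counted. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. At an unadjusted p under 0.05, model against control gave 2245 probe sets and the highest other split 1286 (1 of 10 gave as many, the real one included). Drug against model gave 610 and the highest other 3003 (5 of 10), and drug against control 1345 and 3369 (3 of 10). Those highest splits set drug 1 beside model 1 and model 2, and beside control 1 and control 2, and point to a structure of the samples other than the groups. With the Gapdh term the real counts were 1573, 1083 and 1595. For gene lists the real counts were 7, 6 and 6 and the highest others 9, 12 and 8 (6 of 10 in each comparison). Over the 3 groups the F test gave 1387 probe sets, 21 of 100 splits, the real one included, gave as many and the highest other gave 5068, so chance was not excluded. That split put control 1, model 1 and drug 1 together, and model 3, drug 2 and drug 3 together.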
